A study of Mus musculus with 30 samples.

How the data were processed

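Astrocytes were sorted for green fluorescent protein from brains of young adult male mice of an Aldh1l1-eGFP line, in which astrocytes carry the reporter. Stroke was made by middle cerebral artery occlusion (MCAO) for 1 hour with reperfusion, with sham surgery as its control, and cells were taken 1, 3 or 7 days later. Neuroinflammation was made by an intraperitoneal injection of 5 mg/kg lipopolysaccharide (LPS), with saline as its control, and cells were taken after 1 day. About 20 ng of RNA per sample was amplified in a 2-cycle protocol and hybridised to an Affymetrix mouse expression array. There were 30 arrays in 8 groups. The 1-day groups held 5 MCAO, 4 sham, 5 LPS and 4 saline arrays, and each group of 3 and 7 days held 3 arrays.

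The deposited table holds 1 intensity per probe set and array, normalised by the authors with RMA (version not stated) and given as whole numbers from 9 to 35553. Intensities were on the linear scale, so log2 was taken. Of 45037 probe sets, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none. Gene identifiers of 34741 of those with 1 symbol matched the RefSeq table of GRCm38.p6, and 0 symbols changed through it. For each of 18193 genes the probe set with the highest mean over the 30 arrays was used. Genes at a log2 intensity of at least 5 (32 on the linear scale) on at least 3 arrays were kept, which left 15726 genes and set 2467 aside. Raw scanner files were not used here, so background correction and probe summaries are those of the authors. Arrays have no read depth, and their number limits the precision. The labels call the arrays biological replicates without saying whether each is of a separate mouse, so p-values measure the spread between these samples alone.

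Differences were tested with limma 3.58.1 in R 4.3.3, with 1 linear model over the 8 groups, no intercept, and moderated variances (22 residual and 4.55 prior degrees of freedom). SE and p-values of a comparison thus rest on a variance pooled over the 8 groups, not on the spread of the compared arrays alone. The spread between arrays differed between groups. Each MCAO group was compared with the sham group of its day and LPS with saline. Differences between these effects were tested as interaction contrasts of the MCAO and LPS effects at 1 day and of the MCAO effects at 3 against 1, 7 against 3 and 7 against 1 day. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of that contrast, and "higher", "lower", "rose" and "fell" are used of called genes. All tests were 2-sided.

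Gene groups were 19 lists of astrocyte and injury programmes and 11 lists of markers of other cells that a sort could hold, 468 genes in all, of which 423 were measured. The programmes were pan-reactive, LPS-type (A1) and MCAO-type (A2) reactive astrocyte genes, astrocyte homeostatic genes, cholesterol biosynthesis, interferon-stimulated genes, MHC class I antigen presentation, complement, cytokines and chemokines, interleukin-6 family and STAT3 targets, cell cycle, extracellular matrix and proteolysis, cytoskeleton, oxidative stress and metallothioneins, glycolysis and hypoxia, glucocorticoid-responsive genes, heat shock and unfolded protein response, immediate early genes, and synapse formation and elimination. Marker lists covered microglia and macrophages, neutrophils and monocytes, T and NK cells, oligodendrocytes, oligodendrocyte precursors, neurons, endothelial cells, pericytes and smooth muscle, fibroblasts, ependymal cells and erythroid cells. Erythroid markers were not tested because too few were measured, which left 29 lists. The pan-reactive, A1 and A2 lists were chosen by the study on these samples and give no independent evidence. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 29 lists of a comparison. Estimating the correlation within each list, and the directional test fry, were alternatives. Counts of members are given over all genes and adjusted over the list alone.

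Named genes followed a rule. Per comparison with a control it took the 10 largest rises and 5 largest falls among called genes whose arrays of both groups did not overlap, then Gfap, Vim, Lcn2, Serpina3n and Aldh1l1, then up to 3 called members per list. It also took 5 genes each way per difference of effects, and up to 5 genes called the same way in all 4 comparisons. Comparisons, lists, this rule and the alternatives were fixed before the data were examined, apart from those named next.

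Alternatives were quantile normalisation, median centring, other filters and probe set choices, robust trended variances, array weights, fits on the compared groups alone, stricter thresholds, replicate numbers as blocks, and leaving out each array in turn. Chosen after seeing the data were the set of arrays described next (as a covariate, with and without quantile normalisation, and each set alone), LPS array 5 out of the whole fit, all 40 choices of 3 MCAO and 3 sham arrays of 1 day, list medians without doubtful arrays, and the description numbers as blocks in the 1-day surgery arrays alone, which loses MCAO array 1 because no sham array holds its number. The highest intensities parted the arrays into a bright set of 16, with maxima of at least log2 14.94, and a dim set of 14, with maxima of at most log2 14.70. All 1-day MCAO and sham arrays, LPS arrays 1 to 3, saline arrays 1 and 2, and array 3 of both 3-day groups were bright, and all other arrays were dim. Numbers in the descriptions may pair the 1-day surgery arrays, but this is not established. The deviations of MCAO and sham arrays with 1 number from their group means were correlated across genes. The values were 0.23, 0.19, 0.50 and 0.16 for numbers 2 to 5. For numbers 3 and 5 the array with the same number was not the best partner. Numbers in the titles gave 0.15, -0.10, -0.24 and -0.11 in the 1-day surgery arrays, so they do not pair these arrays. At 3 days description numbers 1 to 3 gave 0.19, 0.03 and 0.21, and at 7 days 0.37, 0.31 and 0.004. LPS and saline arrays with description number 3 gave 0.31. Genes are not independent replicates.

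The steps were tested on simulated data of the same size, with 50 genes changed per fold size in each comparison of 15726 genes. Errors were drawn independently for each gene, with the same spread on all arrays. The real groups differed in spread, so the rates below need not hold for the real comparisons. For changes of log2 0.5, 1, 2 and 4 the share recovered was 12%, 66%, 96% and 100% for MCAO at 1 day, 4%, 46%, 92% and 100% at 3 days, 4%, 54%, 88% and 100% at 7 days, and 12%, 60%, 86% and 98% for LPS. False calls were 7.43%, 3.97%, 6.82% and 3.76% of the calls of these 4 comparisons. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.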

Results

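The data were 1 whole-transcriptome profile of sorted astrocytes per array. Median intensities lay between 68 and 73 on 29 arrays and at 94 on LPS array 5. Arrays of a group correlated across genes with a median r of 0.937 after LPS and 0.965 after saline. At 3 days it was 0.949 after MCAO and 0.975 after sham surgery, and in the other 4 groups it ran from 0.985 to 0.991. Genes are not independent replicates. LPS array 5 differed more than 2-fold from the mean of the other LPS arrays in 5581 genes. Aldh1l1, whose promoter drives the sorted reporter, was not called in any comparison, with log2 folds of -0.31 after MCAO at 1 day, 0.03 at 3 days, 0.06 at 7 days and 0.07 after LPS.

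What a stroke does to astrocytes within a day was asked by comparing 5 MCAO with 4 sham arrays. Lcn2, which encodes a secreted iron-carrier-binding protein of the acute phase, rose by log2 7.83 ± 0.69 SE (adjusted p = 2.97e-08), from 5.65 ± 1.27 (SD, n = 4) after sham to 13.48 ± 0.25 (SD, n = 5). Lcn2 lay between 4.91 and 5.09 on 3 sham arrays, at the filter of log2 5, and at 7.55 on sham array 3, without which the fold was log2 8.47, so its size is not exact. Intermediate filament genes that mark reactive astrocytes rose as well, Vim 8.68-fold (log2 3.12 ± 0.49) and Gfap 3.22-fold (log2 1.69 ± 0.40). Serpina3n, a secreted serine protease inhibitor, rose 9.09-fold (log2 3.18 ± 0.33).

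The other largest rises at 1 day, without overlap between the arrays, were Ifi202b (log2 6.43), the metalloreductase gene Steap4 (from a mean of 5.36 to 11.36), Tgm1 (5.79), the sphingosine phosphate receptor S1pr3 (5.51), the pentraxin Ptx3 (5.46), S100a10 (5.33), the sphingosine kinase Sphk1 (5.32), the metalloproteinase inhibitor Timp1 (5.26) and Cd109 (5.15). Their SE ran from 0.48 to 0.89. Sham means of Ifi202b (5.29), Steap4 and Sphk1 (5.79) were near the filter of log2 5, which leaves the size of these folds uncertain. With the mean of its probe sets Steap4 rose by 3.56. The largest falls were Gdf10, a ligand of the TGF-beta family (log2 -3.50 ± 0.40), Dhrs3, an enzyme of retinoid metabolism (-2.58 ± 0.28), Abhd1 (-2.54 ± 0.31), Pdzph1 (-2.38 ± 0.49) and Hapln1, a link protein of the perineuronal matrix (-2.31 ± 0.42).

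All 13 pan-reactive and all 12 MCAO-type members rose at 1 day, with median log2 folds of 3.69 and 5.10, and the same numbers rose when adjusted over the list alone. Both lists passed camera with an estimated correlation (adjusted p = 0.00966 each), but they were chosen by the study on these samples and are not independent evidence. Of 9 measured LPS-type members, also chosen on these samples, 5 rose (6 adjusted over the list alone, median 1.69, adjusted p = 0.0291 with an estimated correlation). They included the guanylate-binding protein Gbp2 (4.10), the complement inhibitor Serping1 (2.70) and Fbln5 (1.69).

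Genes of interleukin-6 family signalling rose together at 1 day, 12 of 16 with 1 falling (13 and 1 adjusted over the list alone). Il6 rose by log2 4.46, Clcf1 by 4.22 and the oncostatin M receptor Osmr by 3.68. Il6 and Clcf1 had sham means of 4.52 and 4.87, under the filter of log2 5, so the size of their folds is uncertain. Sham array 3 stood above the other sham arrays on this list (8.71 against at most 7.94) and on Osmr (11.89 against at most 9.12). It did so too on the pan-reactive (9.51 against 8.01), matrix (9.15 against 8.69), glycolysis (10.99 against 10.33), neuron (9.01 against 7.65) and endothelial lists (8.94 against 7.65), and list tests without it were not run. The interleukin-6 list kept its call with an estimated correlation (adjusted p = 0.015). So did cytokines and chemokines (9 of 23 rose and 2 fell, as over the list alone, adjusted p = 0.0388), in which the interferon-induced chemokine Cxcl10 rose by 3.89. Of 21 cytoskeletal genes 14 rose (17 adjusted over the list alone, adjusted p = 0.0207), with Anxa2 (3.53), Tubb6 (3.53) and S100a10. Extracellular matrix genes rose in 12 and fell in 3 of 31 cases (14 and 3 adjusted over the list alone, adjusted p = 0.0327). The hyaluronan receptor Cd44 rose by 3.69 and the proteoglycan Vcan by 2.35.

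Oxidative stress genes rose in 6 of 15 cases (8 adjusted over the list alone, adjusted p = 0.015 with an estimated correlation). The haem oxygenase Hmox1 rose by log2 3.80, Srxn1 by 3.45 and the thioredoxin reductase Txnrd1 by 2.74. Of 18 heat shock and unfolded protein genes 7 rose (9 adjusted over the list alone, adjusted p = 0.0291 with an estimated correlation). They included the small heat shock protein Hspb1 (4.22), Chac1 (3.37) and Atf3 (1.92). Interferon-stimulated genes rose in 9 of 30 cases (16 adjusted over the list alone, median 1.20), but adjusted p = 0.262 with an estimated correlation. Oasl2 rose by 2.51 and Gbp3 by 2.39. Of 13 MHC class I genes the immunoproteasome subunit Psmb8 rose by 1.52 (1 adjusted over the list alone, adjusted p = 0.353 with an estimated correlation).

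Genes of resting astrocytes were among those that fell. Of 28 homeostatic genes 8 fell (12 adjusted over the list alone, median -0.50), with adjusted p = 0.307 with an estimated correlation. They included the glutamate receptor subunit Grin2c (-1.58), Pla2g7 (-1.36) and the organic anion transporter Slco1c1 (-1.20). Of 20 cholesterol synthesis genes 5 fell (10 adjusted over the list alone, median -0.69), with adjusted p = 0.132 with an estimated correlation. Among them were Mvd (-1.60), Tm7sf2 (-1.44) and Nsdhl (-1.15).

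Some lists did not pass camera at 1 day although single members changed. In glycolysis and hypoxia 3 of 19 fell and 1 rose (the same adjusted over the list alone), with the angiogenic factor Vegfa at -1.24, P4ha1 at -1.04 and the hexokinase Hk2 at 1.08. In synapse formation and elimination 2 of 15 rose, Thbs2 (2.66) and Thbs1 (1.44), and 3 fell, Gas6 by -1.24 (2 and 4 adjusted over the list alone). The synapse list had a median of -0.05 and a mean of 0.08. Of 7 complement genes 3 rose, including C1s1 (1.78) and C1ra (1.26), and 1 fell (the same over the list alone). Cdkn1a (2.56) of 13 glucocorticoid-responsive genes and Ier3 (2.58) of 13 immediate early genes rose, with 2 higher and 1 lower and 1 higher adjusted over the list alone. Of 30 cell cycle genes 0 were called by limma, over all genes or over the list alone, and camera gave adjusted p = 0.428. Marker lists of other cells did not pass either. The called members for microglia and macrophages were Cd68 (1.98, 1 of 14). Others were Il1r2 (0.87) and S100a8 (0.87, 2 of 12) for neutrophils and monocytes, Vwf (1.57, 1 of 13) for endothelium, Tagln (1.53, 1 of 9) for pericytes and smooth muscle. Lower were Aspa (-1.17) and Cnp (-0.69, 2 of 11) for oligodendrocytes and Cacng4 (-1.12, 1 of 8) for their precursors. Adjusted over the list alone these counts were the same except for endothelium, with 1 higher and 3 lower. T and NK cell, neuron, fibroblast and ependymal lists had 0 called members in limma (median log2 folds of -0.06, -0.43, -0.11 and -0.14), and over the list alone 2 fibroblast markers were lower. Median and mean differed in sign for the cell cycle (-0.02 and 0.09), microglia (-0.01 and 0.10), oligodendrocyte precursors (0.03 and -0.09) and endothelium (0.13 and -0.10), and camera pointed up for pericytes (-0.12).

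In limma 1991 of 15726 genes were called at 1 day, 1021 higher and 970 lower, and 596 and 421 of them by at least 2-fold. The arrays of both groups did not overlap in 27.3% of genes, against 1.59% by chance. With the description numbers as blocks in the 1-day surgery arrays 1218 genes were called, 700 of them higher. Calls then ended for Oasl2 (adjusted p = 0.0515), Psmb8 (0.068), C1ra (0.0993), Hk2 (0.068), Atf3 (0.0604), S100a8 (0.129) and Cacng4 (0.0582). Every list kept its side of the threshold. This fit also loses MCAO array 1, whose number no sham array holds. Leaving out that array alone gave 1424 genes and already ended the calls of C1ra (adjusted p = 0.0668) and S100a8 (0.0911), while the other 5 kept theirs. Calls of single genes were fragile in other ways. Without 1 of the 9 arrays in turn the calls of C1ra and S100a8 ended in all 9 cases, those of Vwf and Psmb8 in 6, Cnp in 4, Oasl2 in 3, Atf3 and Vegfa in 2 and Hk2 in 1. Vwf and Cnp had adjusted p = 0.0675 and 0.0599 when the 9 arrays were fitted alone, and Cnp 0.0537 without shared probe sets. Sham means were under log2 5 for C1ra (4.56), S100a8 (4.67) and Thbs1 (4.73) and close to it for Oasl2 (5.02), Cd68 (5.34), C1s1 (5.47) and Thbs2 (5.57), so the size of these folds is uncertain as well. Leaving out any 1 of the 9 arrays gave 1367 to 1914 genes, and 3 against 3 arrays gave 539 to 1669 over 40 choices. Other settings raised the number, among them the compared groups alone, array weights and description numbers as blocks in all arrays, as given in the part on processing.

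**Figure D1:**
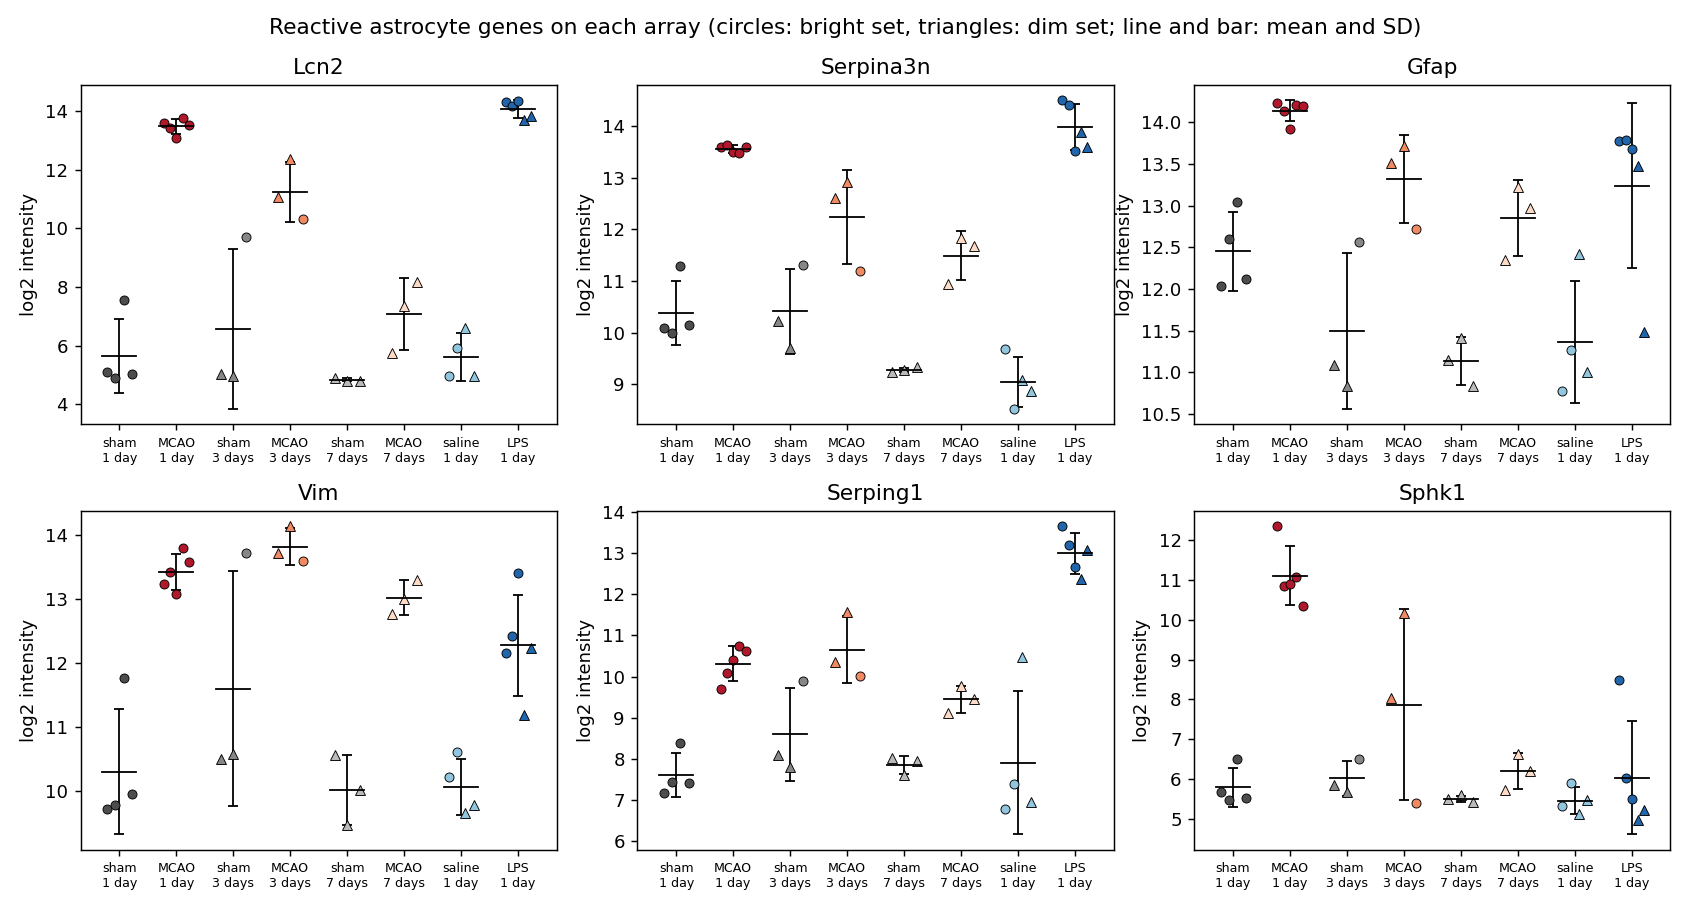
Log2 intensity of 6 genes on each array (circles for the bright and triangles for the dim set), with the mean (line) and SD (bar) of each of the 8 groups. Lcn2 averaged 13.48 at 1 day, 11.25 at 3 days and 7.09 at 7 days after MCAO and 14.07 after LPS, while Sphk1 averaged 11.11 at 1 day after MCAO.

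How far the response lasts was asked with 3 MCAO and 3 sham arrays at each of 2 later times. At 3 days Lcn2 was still higher (log2 4.68 ± 0.83 SE, adjusted p = 0.00893), at 11.25 ± 1.03 against 6.57 ± 2.71 (SD, n = 3 each), with sham array 3 at 9.70. Of 30 cell cycle genes 6 were higher. They included Cdc20, an activator of the anaphase-promoting complex (log2 2.22), the mitotic kinase Cdk1 (2.12) and the ubiquitin-conjugating enzyme Ube2c (2.01). When the 6 arrays were fitted alone, adjusted p was 0.437 for Lcn2, Cdc20 and Ube2c and 0.44 for Cdk1. These calls thus rest on the variance pooled over the 8 groups. Gfap (log2 1.82 ± 0.49, adjusted p = 0.083) and Vim (2.22 ± 0.60, adjusted p = 0.0879) were not called. Arrays 1 and 2 of both groups carried these differences, and array 3 of the MCAO group and array 3 of the sham group lay together.

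Other large rises at 3 days were Tgm1 (log2 4.29), Timp1 (3.83), S100a10 (3.66), Anxa3 (3.20), the galectin Lgals3 (3.17), Anxa2 (3.01), the secreted neuropeptide precursor Vgf (2.77), the transcription factor Klf5 (2.68) and Hspb1 (2.66), and Serpina3n rose by 1.83. Falls were smaller, with 1700012D14Rik at -1.53, the Wnt receptor Fzd2 at -1.37, Cyp4f15 at -1.20, Masp1 at -1.11 and D030055H07Rik at -1.11. Masp1 turned to 0.20 without probe sets marked as shared between transcripts and had -0.48 (adjusted p = 0.277) with the mean of its probe sets. Klf5 had 0.99 (0.0579) with that mean, and Cdc20 1.77 (0.0662) without shared probe sets, so these 3 calls rest on the choice of probe set.

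With an estimated correlation 4 lists passed camera at 3 days, each at adjusted p = 0.0406. Cell cycle genes rose in 6 of 30 cases (23 adjusted over the list alone, median 1.27) and cytoskeletal genes in 5 of 21 (14 adjusted over the list alone, median 1.45). Pan-reactive genes rose in 4 of 13 cases (11 adjusted over the list alone, median 2.09) and MCAO-type genes, among them Tm4sf1 (3.12) and Clcf1 (2.60), in 5 of 12 (8 adjusted over the list alone, median 2.48). Both lists were chosen on these samples and are not independent evidence. In the dim arrays alone (2 against 2) these medians were 2.27, 2.29, 3.26 and 3.86, and in the bright pair (1 against 1, a value without a spread of its own) -0.38, -0.04, -0.11 and -0.45. The set as a covariate cannot move these folds, since each 3-day group held 1 bright and 2 dim arrays. Oligodendrocyte markers moved with the same arrays, with median log2 folds of 2.54 in the dim arrays and -0.65 in the bright pair, and their precursors with 1.13 and -0.47.

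Other lists passed camera at 3 days only with the preset correlation, and with an estimated correlation had adjusted p = 0.233 for LPS-type genes (0 of 9 called, 3 adjusted over the list alone, chosen on these samples and so not independent evidence), interferon-stimulated genes (0 of 30, 6 adjusted over the list alone), cholesterol synthesis, complement, cytokines, and pericytes and smooth muscle, in which Tagln rose by 2.46. It was 0.172 for interleukin-6 family genes, 0.285 for matrix genes, 0.327 for homeostatic and for heat shock genes, 0.328 for MHC class I genes, 0.375 for oligodendrocyte precursors and 0.458 for oligodendrocytes (median 1.26, 0 of 11 called in limma and 0 adjusted over the list alone). Lists of oxidative stress, glycolysis, glucocorticoid, immediate early and synapse genes, microglia, neutrophils, T and NK cells, neurons, endothelium, fibroblasts and ependyma did not pass either form (median log2 folds from -0.04 to 0.36). Median and mean differed in sign for synapse genes (0.05 and -0.01) and T and NK cells (-0.02 and 0.09), and camera pointed down for glucocorticoid genes (0.01).

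In limma 106 genes were called at 3 days, 96 higher and 10 lower, and 1499 had an unadjusted p under 0.05. Arrays did not overlap in 12.7% of genes, where chance gives 10%. The call rested on single arrays. There were 15 genes without MCAO array 1, 9 without MCAO array 2, 650 without MCAO array 3, 4 without sham array 1, 3 without sham array 2 and 314 without sham array 3. There were 0 when the 6 arrays were fitted alone. With the set as a covariate, which alters the variance alone here, 150 genes were called, in the dim arrays alone 867 and in the bright pair 0.

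At 7 days astrocytes after MCAO still held higher Serpina3n (4.64-fold, log2 2.21 ± 0.41, adjusted p = 0.0398), at 11.49 ± 0.48 against 9.28 ± 0.04 (SD, n = 3 each), with all 3 MCAO arrays above all sham arrays. The matrilin gene Matn4 rose 6.36-fold (log2 2.67 ± 0.38, adjusted p = 0.00137). Rgs16, a regulator of G protein signalling, rose 3.79-fold (1.92 ± 0.35) and C1ql1, a secreted protein of the C1q family, 3.52-fold (1.81 ± 0.21, adjusted p = 6.21e-05). Vim (3.01 ± 0.60, adjusted p = 0.0536), Gfap (1.72 ± 0.49, adjusted p = 0.417) and Lcn2 (2.25 ± 0.83, adjusted p = 1) were not called.

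Markers of oligodendrocyte precursors were higher as a list at 7 days (median 0.89, adjusted p = 0.00118 with an estimated correlation), with 1 of 8 called, C1ql1, and 5 adjusted over the list alone. All 8 had positive folds, with Lhfpl3 at 2.48 and Pdgfra, the receptor that marks precursors, at 2.34. These 2 were named after their values were seen, and neither was called over all genes. Lists of reactive genes also passed with an estimated correlation. Pan-reactive genes (1 of 13 called, 10 adjusted over the list alone, median 2.14) had adjusted p = 0.00327, MCAO-type genes (0 of 12, 7 adjusted over the list alone, median 2.09) 0.00862 and LPS-type genes (0 of 9, 0 adjusted over the list alone, median 1.59) 0.0148, all 3 chosen on these samples and so not independent evidence.

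The same held for the cytoskeleton (8 of 21 adjusted over the list alone, median 0.97, adjusted p = 0.00862), matrix (5 of 31 adjusted over the list alone, median 0.42, 0.00787), interleukin-6 family (3 of 16 adjusted over the list alone, median 0.82, 0.00862), cytokines (5 of 23 adjusted over the list alone, median 0.18, 0.0428) and heat shock lists (1 of 18 adjusted over the list alone, median 0.38, 0.0294). Cell cycle (median 0.68, 0.0428), complement (0.50, 0.0428) and, lower, cholesterol synthesis (-0.38, 0.0333) passed with 0 members called in limma over all genes or over the list alone. Interferon-stimulated, MHC class I, immediate early, glucocorticoid, pericyte, fibroblast and ependymal lists lost their call, with adjusted p = 0.121, 0.192, 0.0717, 0.336, 0.174, 0.285 and 0.431 with an estimated correlation. The glucocorticoid list had a median of 0.01 and a mean of 0.40, and its median turned to -0.05 with arrays centred on their medians. Homeostatic, oxidative stress, glycolysis and synapse genes and markers of microglia, neutrophils, T and NK cells, oligodendrocytes, neurons and endothelium did not pass (median log2 folds from -0.27 to 0.19). Median and mean differed in sign for glycolysis (-0.04 and 0.11), synapse genes (-0.01 and 0.14) and endothelium (-0.01 and 0.04), and camera pointed down for homeostatic genes (0.03) and neutrophils (0.04).

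In limma 4 genes were called at 7 days, all higher, and 412 had an unadjusted p under 0.05, fewer than the 786 that chance would give. The variance was pooled with groups of wider spread, with a median r of 0.937 after LPS against 0.987 and 0.991 at 7 days. The low count thus does not show that a response was absent. Arrays did not overlap in 16.3% of genes, where chance gives 10%. The number was 7 without MCAO array 1 and 2 without MCAO array 2 or without any 1 of the sham arrays 1, 2 and 3. The calls of Serpina3n and Rgs16 ended when any of MCAO arrays 2 and 3 and the sham arrays was left out (adjusted p from 0.137 to 0.426), and that of Rgs16 with the mean of its probe sets (1.17, adjusted p = 0.186). The number of genes was 205 when the 6 arrays were fitted alone, and 17 with the set as a covariate, which alters the variance alone since all 6 arrays were dim.

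**Figure D2:**
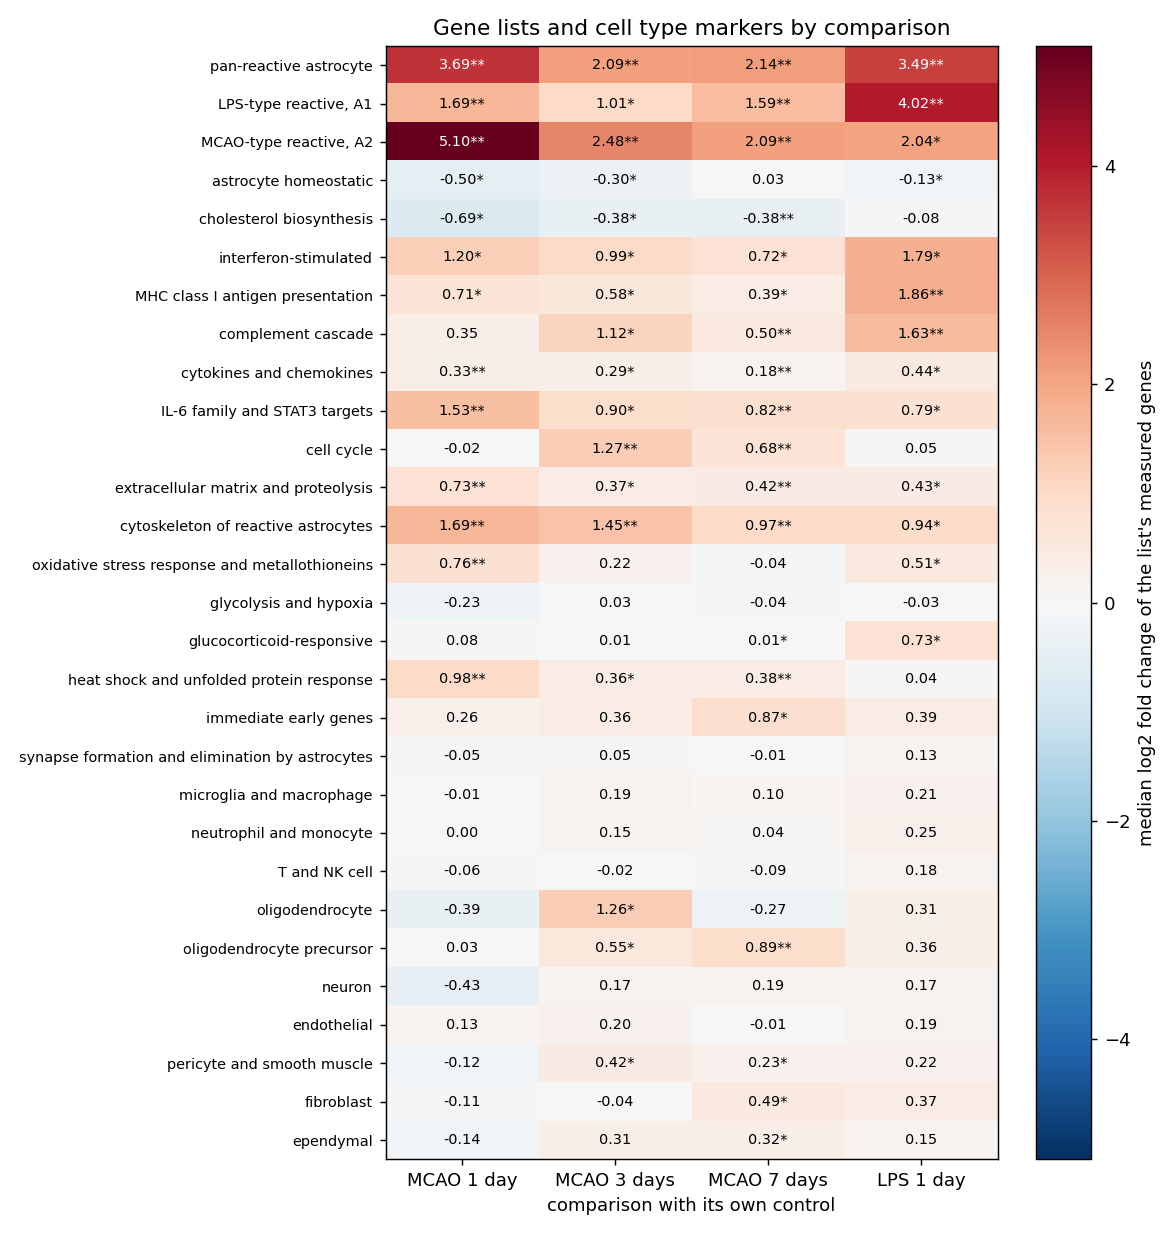
Median log2 fold of each gene list (vertical axis) in the 4 comparisons (horizontal axis), printed and shown as colour. A single star marks camera adjusted p under 0.05 with the preset correlation and a double star also with an estimated correlation, and the pan-reactive medians were 3.69, 2.09, 2.14 and 3.49 for MCAO at 1, 3 and 7 days and for LPS.

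What systemic inflammation does to astrocytes was asked with 5 LPS and 4 saline arrays at 1 day. Lcn2 rose by log2 8.46 ± 0.69 SE (adjusted p = 1.29e-08), from 5.61 ± 0.80 (SD, n = 4) to 14.07 ± 0.29 (SD, n = 5), and Serpina3n 31-fold (4.95 ± 0.33). Antigen presentation and complement genes rose with them. Vim (log2 2.21 ± 0.49) and Gfap (1.87 ± 0.40) rose too, but Vim had 1.69 (adjusted p = 0.0575) with the mean of its probe sets, and Gfap had adjusted p = 0.253 when the 9 arrays were fitted alone. Gfap read 11.48 on LPS array 5 and 13.47 to 13.79 on the other LPS arrays, against up to 12.42 after saline.

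Further large rises after LPS, without overlap between the arrays, were Steap4 (log2 6.29), Timp1 (5.49), Serping1 (5.09), Gbp2 (4.19), the copper-carrying ferroxidase gene Cp (4.15), the elastic fibre gene Fbln5 (4.06), the glucocorticoid-induced chaperone Fkbp5 (4.02) and Lrg1 (3.97), with SE of 0.33 to 0.72. Saline means of Lcn2 (5.61), Steap4 (4.87) and Lrg1 (4.22) were near or under the filter, which leaves the size of these folds uncertain, and Steap4 rose by less, though still called, with the mean of its probe sets. Falls were Chrna7, a nicotinic receptor subunit (-2.59 ± 0.34), Tle2 (-2.16 ± 0.40), Gdf10 (-1.84 ± 0.40), the calcium channel subunit Cacna2d2 (-1.83 ± 0.41) and Sbk1 (-1.79 ± 0.50). Cacna2d2 had -0.53 (adjusted p = 0.15) with the mean of its probe sets.

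With an estimated correlation 4 lists passed camera after LPS. LPS-type genes rose in 8 of 9 cases (8 adjusted over the list alone, median 4.02, adjusted p = 0.000658) and pan-reactive genes in 11 of 13 (13 adjusted over the list alone, median 3.49, adjusted p = 0.00424), both chosen on these samples and so not independent evidence. Complement genes rose in 5 of 7 cases (6 adjusted over the list alone, median 1.63, adjusted p = 0.00222), with C1s1 at 3.84 and C1ra at 3.32. MHC class I genes rose in 9 of 13 cases (11 adjusted over the list alone, median 1.86, adjusted p = 0.0108), with Psmb8 at 3.69, Psmb9 at 3.01 and the peptide-loading factor Tapbp at 2.45. Interferon-stimulated genes rose in 21 of 30 cases (28 adjusted over the list alone, median 1.79), with Iigp1 at 4.19 and Oasl2 at 3.82, but adjusted p = 0.0573 with an estimated correlation. Saline array 3 read 8.82 on the mean of this list, and the other saline arrays read at most 6.72. It also stood apart on the MHC class I mean (9.90 against at most 7.89) and on Serping1 (10.48 against at most 7.40). The same held for Iigp1 (11.94 against at most 5.25) and Oasl2 (9.20 against at most 4.52), so the size of their folds depends on this array. Without saline array 3 the medians after LPS were 2.42 for MHC class I, 2.24 for interferon-stimulated and 1.72 for complement genes. Saline means of C1ra (5.08), Oasl2 (5.66) and C1s1 (5.90) were near the filter. Oasl2 read 4.46 to 4.52 on the saline arrays other than array 3, under the filter of log2 5.

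Between the bright arrays (3 LPS and 2 saline) and the dim arrays (2 and 2), medians after LPS were 4.12 and 2.49 for pan-reactive, 4.51 and 2.79 for LPS-type, 2.71 and 1.03 for MCAO-type, 2.55 and 0.85 for interferon-stimulated, 2.85 and 1.40 for MHC class I and 2.19 and 1.21 for complement genes. With the set as a covariate they were 3.46, 3.99, 1.98, 1.74, 1.81 and 1.66.

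MCAO-type genes, chosen on these samples and so not independent evidence, rose in 4 of 12 cases after LPS (8 adjusted over the list alone, median 2.04), with Cd109 (3.75), the LPS co-receptor Cd14 (2.59) and Tgm1 (2.50), but adjusted p = 0.15 with an estimated correlation. That p was also 0.15 for the cytoskeleton (7 of 21, 12 adjusted over the list alone, with S100a10 at 2.11 and Msn 3.99-fold higher) and for oxidative stress (2 of 15, 3 adjusted over the list alone, Gsr at 2.35 and Fth1 at 0.98). It was 0.148 for interleukin-6 family genes (3 of 16, 7 adjusted over the list alone, Osmr at 2.98, Bcl3 at 2.93 and Cebpd at 1.98) and 0.154 for cytokines (4 of 23, 8 adjusted over the list alone, with Cxcl10 at 3.49, Cxcl1 at 2.31 and Ccl5 at 1.12). For glucocorticoid-responsive genes (3 of 13, as over the list alone, Fkbp5, Cdkn1a at 3.51 and the sulfotransferase Sult1a1 at 1.84) it was 0.154 as well. It was 0.275 for matrix genes (4 rose and 1 fell of 31, 7 and 2 adjusted over the list alone, with Tgm2 at 2.96). For homeostatic genes it was 0.816 (0 of 28 called in limma, 0 higher and 1 lower adjusted over the list alone, median -0.13). Without shared probe sets S100a10 had 1.19 (adjusted p = 0.225) and Cxcl1 2.43 (0.0641). The homeostatic median turned to 0.07 without LPS array 5.

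Lists that did not pass camera after LPS held a few called genes. They were Mvd (-1.35, 1 of 20) in cholesterol synthesis, Hk2 (1.13) and Bnip3 (1.02, 2 of 19) in glycolysis, Hspb1 (3.28, 1 of 18) in heat shock and Ier3 (2.86, 1 of 13) in immediate early genes. Others were Thbs2 (2.16) and Sparc (0.92) with, lower, Megf10 (-0.78, 3 of 15) in synapse formation and elimination, and Rgs5 (1.98, 1 of 9) in pericytes and smooth muscle. Some of these calls were weak. Mvd had -0.52 (adjusted p = 0.472) without shared probe sets and -0.94 (0.0646) with the mean of probe sets. Sparc lost its call with quantile normalisation (adjusted p = 0.0721), without a filter (0.055), with trended variances (0.051) and without 7 of the 9 arrays in turn. Megf10 lost it without 6 of them. Cell cycle genes and markers of microglia, neutrophils, T and NK cells, oligodendrocytes and their precursors, neurons, endothelium, fibroblasts and ependyma had 0 called members in limma (median log2 folds from 0.05 to 0.37), and 1 neutrophil marker was higher over the list alone. Median and mean differed in sign for glycolysis (-0.03 and 0.04), and camera pointed down for neurons (0.17).

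In limma 489 genes were called after LPS, 372 higher and 117 lower, and 240 and 65 by at least 2-fold, while arrays did not overlap in 2.75% of genes against 1.59% by chance. Higher genes made up 76.1% of the calls, and 332 of 505 after quantile normalisation. The number was 307 without LPS array 1, 990 without LPS array 3, 804 without LPS array 4, 225 without saline array 4 and 65 when the 9 arrays were fitted alone. In that last fit 26 named genes lost their call. They were Gbp2 (adjusted p = 0.0589), Fkbp5 (0.098), Iigp1 (0.427), Oasl2 (0.154), Psmb9 (0.134), Tapbp (0.115), Cxcl10 (0.343), Osmr (0.118), Cd14 (0.156), Gdf10 (0.0618), Gfap, Cacna2d2, Sbk1, Tgm1, Cxcl1, Ccl5, Cebpd, Msn, Gsr, Fth1, Hk2, Bnip3, Sult1a1, Sparc, Megf10 and Rgs5. Of 60 named results that use these arrays the calls of 8, 7, 0, 2 and 4 ended without LPS arrays 1 to 5, and of 7, 11, 10 and 16 without saline arrays 1 to 4. Among them Tgm1, Gsr and Bnip3 lost their call after LPS in 6 of the 9 cases and Sbk1 in 5. The number of genes was 836 (520 higher and 316 lower) with the set as a covariate, 368 in the bright and 117 in the dim arrays.

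Which genes respond differently to stroke and to inflammation at 1 day was asked by testing the difference between both effects. Sphk1, the kinase that makes sphingosine phosphate, rose by log2 5.32 after MCAO and had 0.58 after LPS, a difference of 4.74 ± 0.90 (adjusted p = 0.00616). Lgals3 (4.26 ± 0.84), the chromatin protein gene Hmga2 (4.21 ± 0.60), the cytokine gene Clcf1 (3.90 ± 0.63) and the glycosyltransferase gene B3gnt5 (3.64 ± 0.90) also differed towards MCAO. Towards LPS differed Pla2g3 (-2.91 ± 0.66), Sult1a1 (-2.87 ± 0.58), the glutamine transporter Slc1a5 (-2.64 ± 0.60), the adhesion molecule Amigo2 (-2.63 ± 0.66) and Fbln5 (-2.37 ± 0.50). Such a negative difference can hold a fall after MCAO as well as a rise after LPS.

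By list, the difference was positive for MCAO-type genes (4 of 12 called, 9 adjusted over the list alone, median 3.25) and negative for LPS-type genes (2 of 9 called, 6 adjusted over the list alone, median -2.17), lists chosen for this on these samples and so not independent evidence. With an estimated correlation adjusted p = 0.0557 and 0.188. Complement (1 of 7 called, 6 adjusted over the list alone, median -1.75) and MHC class I genes (2 of 13, 8 adjusted over the list alone, median -1.32) differed towards LPS and heat shock (1 of 18, 2 adjusted over the list alone, median 0.97) and cytoskeletal genes (3 of 21, 5 adjusted over the list alone, median 0.91) towards MCAO. These 4 calls ended with an estimated correlation, at adjusted p = 0.0557, 0.252, 0.075 and 0.252, and 0 lists of this difference passed in that form. With the preset correlation alone interleukin-6 family (median 0.52), oxidative stress (0.26), cytokine (0.14) and matrix genes (0.13) also differed towards MCAO. In that form the difference was negative for homeostatic (-0.34), cholesterol synthesis (-0.50) and interferon-stimulated genes (-0.67). Homeostatic and cholesterol synthesis lists held called falls after MCAO and none of their members was called higher after LPS. Pan-reactive genes did not pass, with a median of -0.19 and a mean of 0.31.

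In limma 219 genes differed between the effects, 109 towards MCAO and 110 towards LPS, and 132 of 206 differed towards MCAO after quantile normalisation. The median over all genes was -0.12. With blocks in the 1-day surgery arrays 88 genes differed, and the calls of B3gnt5 (adjusted p = 0.124), Pla2g3 (0.0719), Slc1a5 (0.0584) and Amigo2 (0.131) ended. That fit also loses MCAO array 1. Leaving out this array alone already ended the calls of B3gnt5 (adjusted p = 0.0848), Pla2g3 (0.0565) and Amigo2 (0.0893). Over the 18 arrays left out in turn B3gnt5 and Amigo2 lost their call in 12 cases, Pla2g3 in 5 and Slc1a5 in 4. The compared groups alone ended the calls of Pla2g3 (0.0637), Slc1a5 (0.11) and Amigo2 (0.095). Sham and saline means of Hmga2 (4.95 and 5.19) and Clcf1 (4.87 and 5.30) were near the filter, so the size of their differences is uncertain. The number was 96 and 134 without MCAO arrays 1 and 2, 106, 89 and 99 without sham arrays 1, 2 and 4. It was 469 and 472 without LPS arrays 3 and 5, and 396, 122 and 100 without saline arrays 1, 3 and 4. It was 397 with the set as a covariate and 86 in the bright arrays alone. All 1-day surgery arrays were bright, and 2 LPS and 2 saline arrays were dim, so injury and set are partly confounded here.

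Shared genes were counted as well. Both injuries raised 164 genes at 1 day, where independent lists would share 24.2, and lowered 62, where 7.22 would be shared, while 7 went in opposite directions. Log2 folds of both comparisons correlated across genes with a Pearson r of 0.53 and a Spearman rho of 0.39, and genes are not independent replicates. Serpina3n was the gene called in all 4 comparisons (log2 3.18, 1.83, 2.21 and 4.95), and 18 genes were higher after MCAO at 1 and 3 days and after LPS. Both statements rest on the 3-day calls, which ran from 3 to 650 genes without 1 array. With the 3-day groups fitted alone Serpina3n had adjusted p = 0.437. The number higher in both was 100 without saline array 4. The number lower in both was 36 and 37 without sham arrays 1 and 4, 30, 118 and 108 without LPS arrays 1, 3 and 5, 21 without saline array 4, 34 with blocks in the 1-day surgery arrays (47 without MCAO array 1 alone) and 150 with the set as a covariate.

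**Figure D3:**
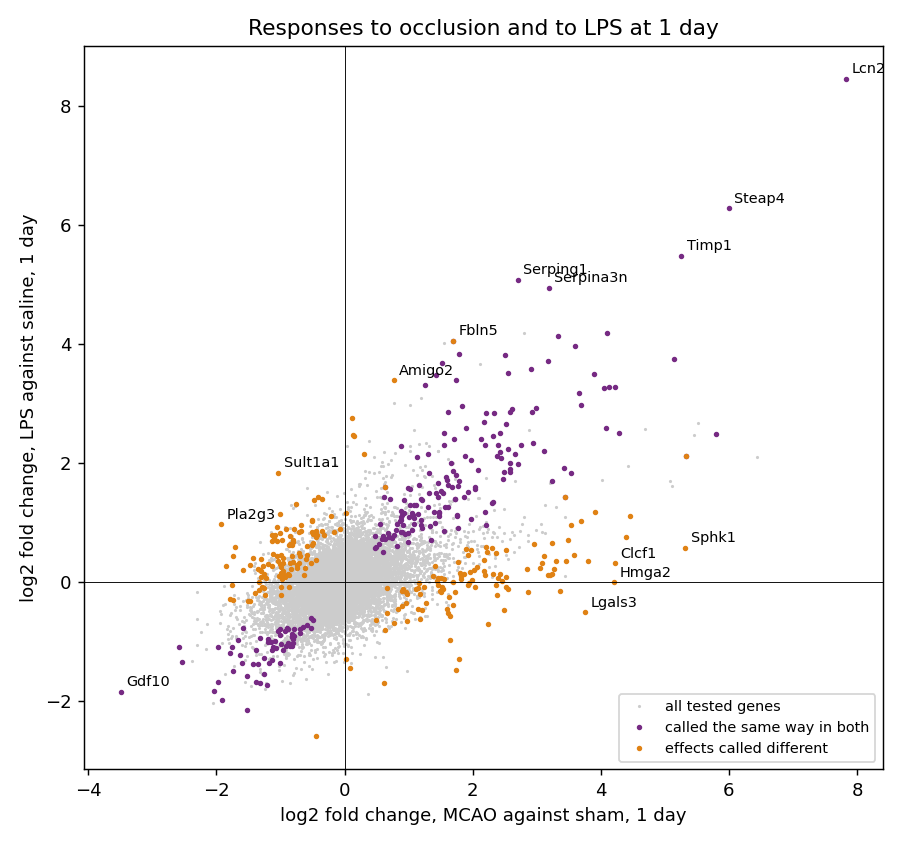
Log2 fold after LPS (vertical axis) against log2 fold after MCAO at 1 day (horizontal axis), 1 point per gene. Purple points are genes called the same way in both, and orange points are genes whose effects differ. Of the genes called in both comparisons 164 lie in the upper right, 62 in the lower left and 7 in the other corners.

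How the stroke response changes with time was asked by testing the MCAO effects of different days against each other. Hmox1, which had risen by log2 3.80 at 1 day, stood at 1.12 at 3 days (difference -2.67 ± 0.44, adjusted p = 0.0249) and at -0.09 at 7 days (difference -3.88 ± 0.44, adjusted p = 2.86e-05). From 1 to 7 days the effects of Lcn2 (-5.58 ± 1.08), Steap4 (-5.07 ± 0.91), Sphk1 (-4.63 ± 1.01) and Hmga2 (-3.91 ± 0.67) fell as well. Upward differed Dhrs3 (2.23 ± 0.43), Farp2 (2.09 ± 0.40), the AMPA receptor subunit Gria4 (1.89 ± 0.42), C1ql1 (1.89 ± 0.27) and Hhatl (1.74 ± 0.35). Of these Dhrs3, Farp2 and Hhatl had fallen at 1 day (-2.58, -1.58 and -1.73). All 1-day surgery arrays were bright and all 7-day arrays dim, so day and set cannot be told apart here. Own controls cancel only an additive shift, and the pan-reactive difference of LPS and saline was 4.57 in the bright and 2.91 in the dim set.

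With an estimated correlation the effect at 7 days differed from that at 1 day in 3 lists. Oxidative stress genes were lower (2 of 15 called, 6 adjusted over the list alone, median -0.78, adjusted p = 0.00951), MCAO-type genes were lower (2 of 12, 11 adjusted over the list alone, median -2.66, 0.0468, chosen on these samples and so not independent evidence) and markers of oligodendrocyte precursors were higher (1 of 8, 4 adjusted over the list alone, median 1.48, 0.0468). At 3 days against 1 day the oxidative stress list was lower (1 of 15 called, 6 adjusted over the list alone, median -0.66, adjusted p = 0.0256). Cell cycle genes differed upwards there with the preset correlation (0 of 30 called in limma, 15 adjusted over the list alone, median 1.24), but adjusted p = 0.124 with an estimated correlation.

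In limma 56 genes differed between 7 days and 1 day (10 upwards and 46 downwards), 1 between 3 days and 1 day, which was Hmox1, and 0 between 7 and 3 days, where 274 had an unadjusted p under 0.05. Of the 1021 genes higher at 1 day, 957 had a positive fold at 3 days and 842 at 7 days, with median log2 folds of 1.13, 0.51 and 0.24. Choosing genes by their call at 1 day favours that day, so this does not measure a decline. The 96 genes higher at 3 days had medians of 1.76 at 3 days and 1.31 at 1 day, and the 4 genes higher at 7 days 2.07 at 7 days and 1.06 at 1 day. With blocks in the 1-day surgery arrays 25 genes differed at 7 days and 5 at 3 days. The calls of Dhrs3 and Farp2 (adjusted p = 0.0549 each), Gria4 (0.0843) and Sphk1 (0.123) at 7 days ended. That fit also loses MCAO array 1 of 1 day, and leaving out this array alone ended those of Gria4 (0.0807) and Sphk1 (0.079). Over the 15 arrays left out in turn the call at 7 days ended in 12 cases for Sphk1, 11 for Gria4, 7 for Hhatl and 4 each for Lcn2, Dhrs3 and Farp2. That of Lcn2 ended without MCAO array 1 of 7 days (adjusted p = 0.0945) and without any of the sham arrays of 7 days (0.0557 to 0.0593). Gria4 had 0.71 (adjusted p = 0.244) with the mean of its probe sets and Farp2 0.95 (0.309) without shared ones. The call of Hmox1 at 3 days against 1 day ended in 6 of 15 cases. They were MCAO array 1 (adjusted p = 0.0626) and sham arrays 1, 2 and 4 of 1 day (0.0646, 0.0815 and 0.0877), and MCAO array 1 (0.0986) and sham array 2 of 3 days (0.0893). It also ended when the compared groups were fitted alone (0.132). For 7 days against 1 day the number was 33 without MCAO array 1 of 1 day, 28, 29 and 22 without sham arrays 1, 2 and 4 of 1 day. It was 17 without MCAO array 1 or 3 of 7 days, and 20, 17 and 15 without sham arrays 1, 2 and 3 of 7 days. For 3 days against 1 day it was 0 without MCAO array 1 or sham arrays 1, 2 or 4 of 1 day or sham array 2 of 3 days, and 7, 3 and 10 without MCAO arrays 3, 4 and 5 of 1 day. It was 4 without sham array 3 of 1 day, 21 and 9 without MCAO arrays 2 and 3 of 3 days, and 27 without sham array 3 of 3 days. For 7 days against 3 days it was 5 without MCAO array 3 of 3 days.

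**Figure D4:**
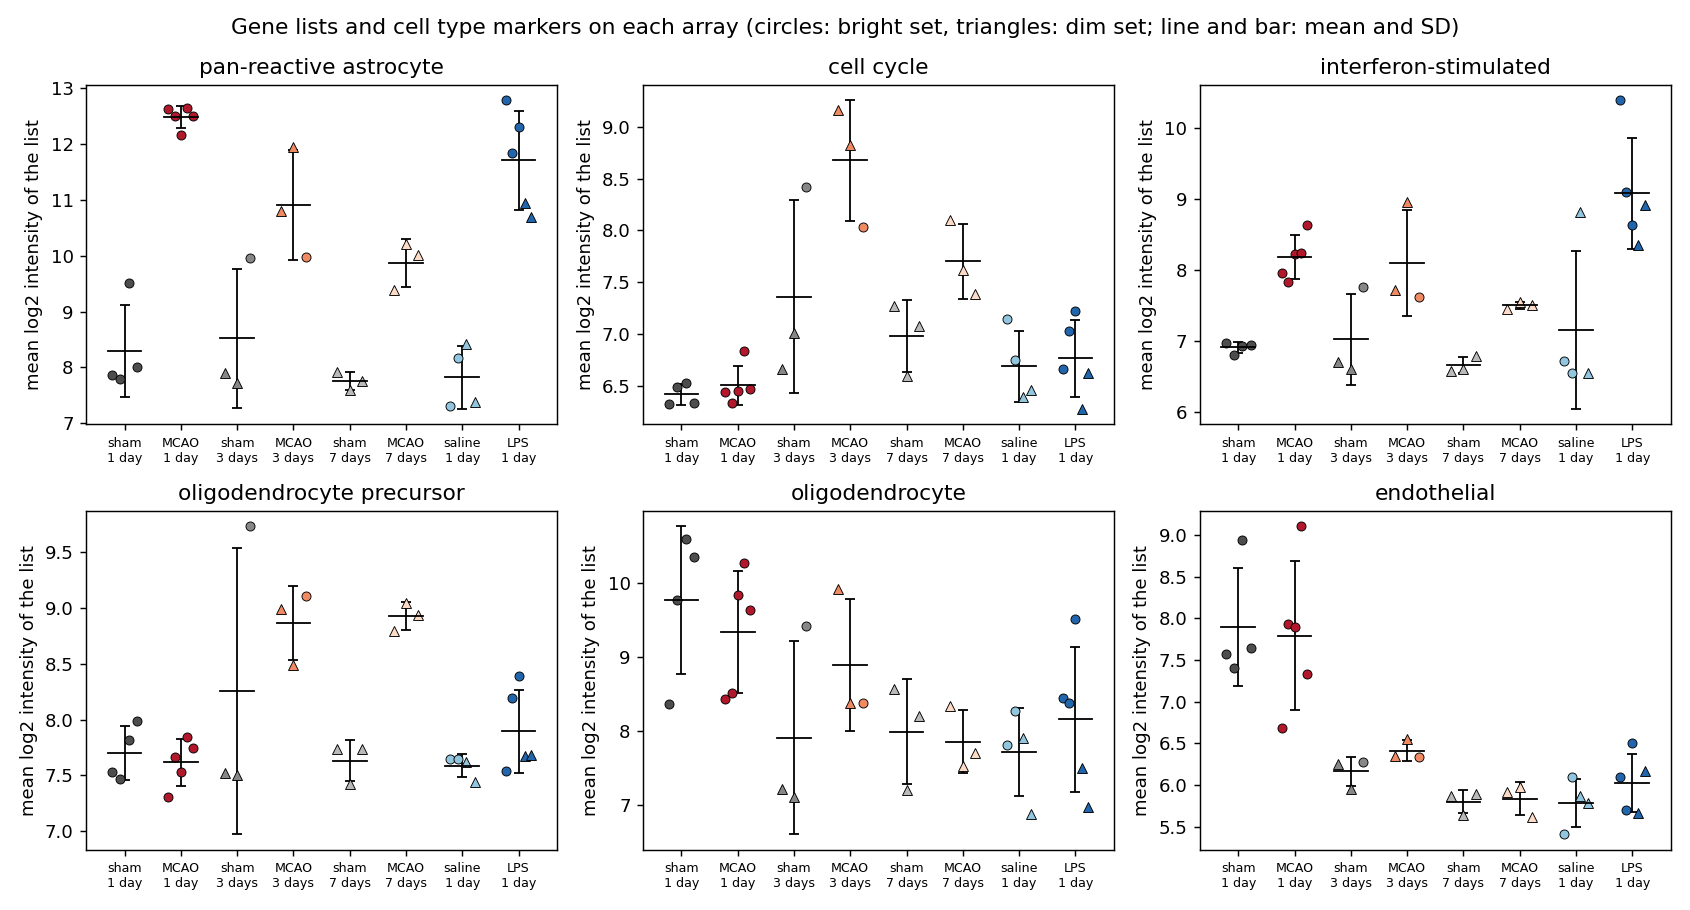
Mean log2 intensity of 6 gene lists on each array (circles for the bright and triangles for the dim set), with the mean (line) and SD (bar) of each group. At 3 days the pan-reactive mean was 9.96 on sham array 3 and 9.98 on MCAO array 3, and 10.80 and 11.95 on the other MCAO arrays.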

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

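The tests of 8 explanations below, and that of LPS splits within the sets, were chosen only after the results were seen, while 10 tests on other splits of the arrays were chosen before.

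Among 372 groups of values of the 1-day arrays tested for an outlying array 39 had one, where 18.6 were expected, since chance flags about 1 in 20 groups. These groups share arrays and are not independent, so the expected number is a rough guide. Arrays of the later days were not tested in this way. In sham array 3 of 1 day reactive genes stood above the other sham arrays, with Lcn2 at 7.55, Steap4 at 6.41, Serpina3n at 11.30, Vim at 11.76, Osmr at 11.89, Anxa2 at 10.49, Tubb6 at 8.82, Hspb1 at 9.53, Ifi202b at 7.04, Psmb8 at 5.95 and Vwf at 8.46. The means of 6 lists were high there too, pan-reactive at 9.51, interleukin-6 family at 8.71, matrix at 9.15, glycolysis at 10.99, neuron at 9.01 and endothelium at 8.94. After MCAO at 1 day Cxcl10 read 11.06 on array 5 and Hk2 9.97 on array 1, the pan-reactive mean was low at 12.16 on array 3, and array 4 was high for the cell cycle (6.83), immediate early genes (11.80) and neurons (8.65). After LPS Bnip3 (10.37) and Gfap (11.48) were low on array 5 and Tapbp (11.26) on array 3, and glycolysis was high on array 2 (10.08). After saline array 3 was high for Cxcl10 (10.36), Iigp1 (11.94), Oasl2 (9.20), Serping1 (10.48), the interferon list (8.82) and MHC class I (9.90). Saline array 1 was low for Cacna2d2 (9.04) and high for glycolysis (9.996) and synapse genes (9.99), array 4 was low for MCAO-type genes (5.52) and oligodendrocyte precursors (7.44), and array 2 was high for neurons (7.76).

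Differences between effects were flagged for 219 genes between MCAO and LPS, 1 gene between 3 days and 1 day and 56 genes between 7 days and 1 day. Named between MCAO and LPS were Sphk1 (4.74), Lgals3 (4.26), Hmga2 (4.21), Clcf1 (3.90), B3gnt5 (3.64), Pla2g3 (-2.91), Sult1a1 (-2.87), Slc1a5 (-2.64), Amigo2 (-2.63) and Fbln5 (-2.37). Between 3 days and 1 day it was Hmox1 (-2.67). Between 7 days and 1 day they were Dhrs3 (2.23), Farp2 (2.09), Gria4 (1.89), C1ql1 (1.89), Hhatl (1.74), Lcn2 (-5.58), Steap4 (-5.07), Sphk1 (-4.63), Hmga2 (-3.91) and Hmox1 (-3.88). Of 5963 probe sets without a gene symbol 96 were called higher and 90 lower in limma after MCAO at 1 day, 1 higher and 0 lower at 3 days, 0 at 7 days, and 23 higher and 17 lower after LPS, and the genes they read were not analysed here.

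In pattern A, MCAO array 3 and sham array 3 of 3 days lay together on the reactive lists, with pan-reactive means of 9.98 and 9.96. An exchange of their labels alone is argued against, because it would turn the difference of the pair negative and not remove it. The median signed difference over the 1991 genes called at 1 day was 0.029, against 0.56 and 0.77 for the pairs 1 and 2. This restates that the arrays lie together, and an exchange on top of another cause was not tested. That the bright set hides differences is argued against by a pan-reactive difference of LPS and saline of 4.57 in the bright and 2.91 in the dim set. A wrong label of sham array 3 stays open, since 9.96 lay above the highest of 13 other control arrays (9.51) and 0.02 below the lowest MCAO array of 3 days (9.98). That lowest array is MCAO array 3 itself, so its closeness restates the pattern, and the other MCAO arrays lay higher, up to 11.95. The test of this label first asked for a value inside the range of the MCAO arrays, which it missed, and a tolerance of 1 SD (0.99) was added after the value was seen.

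In pattern B, saline array 3 read 8.82 on the interferon list, inside the LPS arrays (8.35 to 10.38). A mislabelled LPS array is argued against, because its pan-reactive mean of 8.41 lay 2.27 below the lowest LPS array (10.69, SD 0.89). RNA of immune cells is argued against by an excess of at most 0.15 over the other saline arrays in 3 immune cell lists. A reading particular to the dim set is argued against by 6.79 as the highest of 6 other dim control arrays. What raised interferon genes in this array stays open.

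In pattern C, markers of oligodendrocyte precursors were higher at 7 days. Fewer astrocytes in the sort, with all other cell types rising alike, is argued against. The median difference of 9 other marker lists was 0.077 and that of the precursor list 1.29 (SD 0.16). The 9 lists ran from -0.14 for oligodendrocytes (SD 0.58) to 0.65 for fibroblasts (SD 0.73). A sort in which only some other cell types became more common was not tested. RNA of precursors in the sort would raise most of their markers, and 8 of 8 had positive folds (1 called, 5 over the list alone). This restates the rise of the list and does not separate the explanations. Whether precursors entered the sort or astrocytes changed their own expression stays open, since both could give these values.

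Arrays of compared groups were also split in other ways. For MCAO at 1 day the real split had the most calls, 1 of 100 (1991, highest other 1040), and chance can be excluded in this fit. In the same fit it can be excluded for the difference of MCAO and LPS effects (1 of 100, 219 against 169) and for 7 days against 1 day (1 of 100, 56 against 0). For genes higher (1 of 100, 164 against 10) and lower (1 of 100, 62 against 3) in both, the labels of both comparisons were shuffled together. Most other MCAO splits called no gene, so these counts repeat the MCAO result and do not exclude chance for the overlap. For 3 days against 1 day 3 of 100 splits had as many calls (1 against 1), which is under the threshold set before. Other splits also reached this count of 1, so the test decides little on a single gene. For 7 days against 3 days the real count was 0, so that 100 of 100 splits had as many whatever the data (highest other 29), and this says nothing on chance. At 3 days (2 of 10, 106 against 185) and 7 days (1 of 10, 4 against 0) the splits are too few. For 7 days against 1 day the arrays of each day lay in 1 set, so excluding chance does not part the day from the set. For MCAO against LPS all 1-day surgery arrays were bright, while 2 LPS and 2 saline arrays were dim. Excluding chance thus does not fully part the injury from the set there either. These splits ignored the possible pairs of the 1-day surgery arrays and the sets. They were not run with blocks, where 88 genes differed between MCAO and LPS, so the exclusions hold for the fit without blocks alone. The split with 185 calls put sham array 3 with MCAO arrays 1 and 2.

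For the number of genes called after LPS chance cannot be excluded, since 21 of 100 splits had as many calls (489 against 3100). This tests the count and not single genes, whose own p-values are given above. The split with 3100 calls followed the sets, with the bright LPS and saline arrays against the dim ones, and so points to a structure of the samples. With the set as a covariate and splits within the sets it cannot be excluded either, at 9 of 60 (836 against 3210).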

How the results depend on the processing

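The tests with the set of arrays, with LPS array 5 out of the whole fit, with list medians without doubtful arrays, with 3 against 3 arrays and with blocks in the 1-day surgery arrays were chosen only after the results were seen, and the others before. Over all settings 2744 of the values of named genes stayed called in the same direction or stayed uncalled. Of the others 375 lost the call, 20 gained one and 1 reversed, which was Masp1 at 3 days (0.20 without shared probe sets). Changes of sign in uncalled genes were not counted. List medians kept their size in 450 cases, moved in 30 and reversed in 13. Camera results stayed on their side of the threshold in 195 cases, which include lists that passed under neither setting. Camera calls ended in 65 cases and arose in 1. Counts stayed within 1.5-fold in 168 cases and moved in 132. Except where the construction is given, the cause was not tested. Low signal over background limits genes near the filter, and the number of arrays limits the precision.

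Quantile normalisation gave 14 genes at 7 days and 5 for 3 days against 1 day. Median centring gave 13 and 5, and a glucocorticoid median at 7 days of -0.052. At 7 days there were 2 genes without a filter, 13 with the filter at log2 7 and 17 with robust trended variances. The mean of probe sets gave 7 at 7 days and 16 for 3 days against 1 day. Array weights gave 6161 genes for MCAO at 1 day, 1937 at 3 days, 525 at 7 days, 1660 after LPS, 2123 for MCAO against LPS, 259 for 3 days against 1 day, 222 for 7 against 3 days and 3144 for 7 days against 1 day, with 557 higher and 305 lower in both. The compared groups alone gave 5180 at 1 day, 0 at 3 days, 205 at 7 days, 65 after LPS, 92 for MCAO against LPS, 2 for 3 days and 1537 for 7 days against 1 day, and 26 lower in both.

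A fold of at least 2 left 1017 genes at 1 day, 305 after LPS and 30 lower in both, by construction. An adjusted p under 0.01 left 1096 at 1 day, 12 at 3 days, 2 at 7 days, 197 after LPS, 55 for MCAO against LPS, 0 for 3 days and 13 for 7 days against 1 day, and 80 higher and 12 lower in both. Title numbers as blocks gave 10 at 3 days, 1 at 7 days and 0 for 3 days against 1 day. Description numbers gave 4329 at 1 day, 864 at 3 days, 1 at 7 days, 1832 after LPS, 646 for MCAO against LPS, 24 for 3 days and 589 for 7 days against 1 day, and 294 higher and 593 lower in both. There a number held by 1 array drops that array, and the LPS effect rests on 1 pair. Blocks in the 1-day surgery arrays gave 1218 at 1 day, 88 for MCAO against LPS, 5 for 3 days and 25 for 7 days against 1 day, and 34 lower in both. They lose MCAO array 1, without which alone there were 1424, 96, 0, 33 and 47.

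The set as a covariate gave 17 at 7 days, 836 after LPS, 397 for MCAO against LPS, 6 for 3 days against 1 day and 150 lower in both. With quantile normalisation it gave 210 at 3 days, 17 at 7 days, 837 after LPS, 370 for MCAO against LPS, 12 for 3 days against 1 day and 149 lower in both. Bright arrays alone gave 0 at 3 days, 86 for MCAO against LPS and 58 for 3 days against 1 day. Medians of 11 lists at 3 days reversed there, to -0.11 for pan-reactive, -0.079 for LPS-type, -0.45 for MCAO-type, -0.11 for interferon, -0.29 for interleukin-6, -0.38 for cell cycle, -0.084 for matrix, -0.044 for cytoskeleton, -0.00405 for heat shock, -0.65 for oligodendrocyte and -0.47 for precursor genes. Dim arrays alone gave 867 at 3 days, 44 at 7 days, 117 after LPS and 10 for 7 against 3 days. Without LPS array 5 in the whole fit there were 223 at 3 days, 13 for 3 days and 131 for 7 days against 1 day. With LPS array 5 left out of the LPS comparison the homeostatic median was 0.074. With 3 against 3 arrays at 1 day the median of 40 choices was 947. The 7-day arrays gave no value in the bright set, and the 1-day surgery arrays none in the dim set.

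Leaving out 1 array in turn gave 1367 to 1914 genes at 1 day, 3 to 650 at 3 days, 2 to 7 at 7 days and 225 to 990 after LPS. It gave 89 to 472 for MCAO against LPS, 0 to 27 for 3 days against 1 day, 0 to 5 for 7 against 3 days and 15 to 68 for 7 days against 1 day. Genes higher in both ran from 100 to 239 and lower in both from 21 to 118. At 3 days the calls of 20, 21, 22 and 23 of 26 named results ended without MCAO array 1, MCAO array 2, sham array 1 and sham array 2.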

Other observations

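All tests in this part were chosen only after the result was seen. Sham surgery and saline injection are controls of different kinds, and their 1-day arrays (n = 4 each) were compared by the mean log2 intensity of each list. Glucocorticoid-responsive genes averaged 11.33 ± 0.53 (SD) after sham and 9.99 ± 0.34 after saline, a difference of 1.34. Endothelial markers averaged 7.89 ± 0.71 and 5.79 ± 0.28, oligodendrocyte markers 9.77 ± 1.00 and 7.72 ± 0.59, and markers of pericytes and smooth muscle 8.12 ± 0.38 and 7.00 ± 0.30. Smaller differences without overlap were seen for MCAO-type genes (0.72), glycolysis (0.69), microglia (0.57), matrix (0.49) and oxidative stress (0.40).

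Each of these 9 lists had an exact permutation p of 0.0286 over 70 splits, the smallest possible, and an adjusted p of 0.0921 over 29 lists, so none passed adjustment. An adjusted p under 0.05 would have needed many more lists at this smallest value, so the adjustment says little against single differences. Against the 2 bright saline arrays alone the differences were 1.04 for glucocorticoid-responsive genes, 2.14 for endothelium, 1.72 for oligodendrocytes and 1.08 for pericytes.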
